A study of Homo sapiens with 6 samples.

How the data were processed

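Total RNA from 6 samples of NCM460 cells, 3 control and 3 infected with lentivirus to overexpress TRIB3, was sequenced at 24 h. Groups and replicate numbers were taken from the labels. The deposited values are FPKM, fragments per kilobase of gene model scaled to the library's fragment total, with 1 value per gene symbol and 22501 genes per library. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the GRCh38 build; their versions, the annotation release and the strand setting were not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Of the symbols, 21508 matched a RefSeq gene of GRCh38.p14, which gave the positions printed here.

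The FPKM values of each gene were whole multiples of 1 step. A search for the fragment total that makes them whole gave the same depth, within 0.1%, for 201 of 223 single-exon genes. It gave whole counts within 0.02 of a count for all 22501 genes, of which 15738 were above 0 in all 6 libraries. Of 300 perturbed genes, drawn from those with higher counts in every library, 0 passed. Genes with zeros or low counts were not checked in this way. The recovered counts summed to 34824749, 34787059 and 34421789 for the control replicates and to 34911140, 35477983 and 34765774 for the overexpressing ones, at least 99.71% of the fragment totals. These recovered counts were used for depth, for replicate checks and for alternatives chosen after seeing the data, not for the main test. Replicates of a group differed by more than sampling noise, so each was counted as its own library. The chi-square per degree of freedom was 7.39, 16.78 and 21.0 for control pairs and 3.19, 5.76 and 5.79 for overexpressing pairs. Control libraries thus differed more among themselves, while the main test takes a single variance per gene over both groups.

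The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the 6 libraries, with group as the only term and Benjamini-Hochberg adjustment. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. An exact permutation test of a single value cannot give a p below 0.1 with 3 against 3. In total 33 gene lists were fixed before the data were examined, and 24 of their 698 symbols had no match in the tables used here. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Fry, which tests whether a list's genes move one way without comparing them with other genes, gave an adjusted p of 0.161 at the lowest. Named genes were TRIB3, the 10 largest rises and 10 largest falls among called genes with groups that do not overlap (8 rises passed beside TRIB3), and up to 4 members with the smallest p of each called list and of the integrated stress response, Wnt target and stem cell lists. Of the genes this rule takes, 1 is not reported here.

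The test was tried on simulated counts drawn at the means and depths of this comparison, with 200 genes changed. Over 10635 simulated genes it recovered 56% of those changed by 0.322 on the log2 scale, 93.8% at 0.585, and 100% at 1 and at 2, with 3.4% of its calls false. Remaining members of the integrated stress response list were also given a shift, smaller than any of these changes. Changes of 0.322 in the counts had a median estimate of 0.277 on the log2(FPKM + 1) scale. Simulated genes were drawn independently, and no simulated library was made to stand apart as control replicate 3 does. With 200 genes changed, against 21 called in the real data, the adjusted threshold was also easier to pass. These rates can therefore overstate recovery in the real data. Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no expression filter or a filter of 1 FPKM in 3 libraries, TPM scaling, median-ratio scaling, quantile normalization, no trend, a robust fit (statmod 1.5.0), the replicate number as a block, and leaving out each library. Scaling over nuclear-encoded genes, array weights, voom on the recovered counts and voom with quality weights were added after seeing the data. Figures were drawn with matplotlib 3.10.9.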

Results

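RNA of NCM460 cells, an epithelial line derived from normal human colon mucosa, was sequenced at 24 h. One group of 3 libraries came from control cells and the other group of 3 from cells made to overexpress TRIB3 by lentiviral infection. Unless the control cells received a matching virus, which is not known here, effects of infection and of TRIB3 cannot be told apart. TRIB3 is a pseudokinase of the tribbles family that is itself induced by the integrated stress response. The libraries held between 34421789 and 35477983 fragments counted in genes, and 10638 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries.

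The comparison of TRIB3-overexpressing with control cells addressed the study's question of how TRIB3 acts in the maintenance of intestinal stem cell renewal. TRIB3, on chromosome 20 from 380760 to 397559 (GRCh38.p14), rose from 31.4 ± 4.14 FPKM in control to 89.6 ± 4.16 FPKM in overexpressing cells (SD, n = 3 each). The ratio of the means was 2.85, and the log2 fold change was 1.49 with a standard error of 0.0878 (limma, adjusted p = 0.00018). All 3 overexpressing libraries, at 90.4, 85.1 and 93.3 FPKM, lay above the control libraries at 34.2, 26.6 and 33.3 FPKM. These values do not separate transcripts of the endogenous gene from transcripts of the vector.

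At a limma adjusted p below 0.05, 21 genes changed, of which 9 were higher and 12 lower in overexpressing cells, and 5 of the 21 changed by at least 2-fold on the log2(FPKM + 1) scale. At an unadjusted p below 0.05 there were 1013 genes, where 532 would be expected by chance. Groups did not overlap for 16.9% of the genes, where chance gives 10%. Both chance values are averages, and a single grouping can lie far from them where genes vary together. Neither number was taken for other groupings of the libraries. The number of called genes depended on single libraries: without control replicate 3 it was 133, of which 85 were higher and 48 lower, so that the larger share turned from lower to higher, and without TRIB3-overexpressing replicate 1, 2 or 3 it was 8, 6 and 8. All 21 genes were among the 133. In fits chosen after the data were seen, 111 genes were higher and 78 lower with array weights, and 234 and 130 with voom and quality weights. With no expression filter 14 genes were called, of which 5 were among the 21.

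COX10, which encodes the mitochondrial heme A farnesyltransferase, rose from 9.24 ± 0.419 to 19.5 ± 0.152 FPKM (SD, n = 3 each), 2.11 times the control mean (limma, adjusted p = 5.77e-05). PCNX1, on chromosome 14 from 70907459 to 71115382, rose from 7.30 ± 0.728 to 13.5 ± 0.0926 FPKM, a log2 fold change of 0.81 (limma, adjusted p = 0.00174). The interferon-stimulated gene IFI44 rose by 0.80, from 2.65 ± 0.303 to 5.34 ± 0.343 FPKM (limma, adjusted p = 0.00495). NFKBIA, the inhibitor of NF-kB, rose by 0.44 from 31.0 ± 0.763 to 42.4 ± 3.41 FPKM. The remaining rises were those of the adhesion gene CADM1 at 0.56, the noncoding RNA LINC01004 at 0.54, C6orf15 at 0.53 and the galactosyltransferase gene UGT8 at 0.45. LINC01004 averaged only 0.687 FPKM in control, so its fold change on this scale understates the ratio of the means, which was 2.10.

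Among the falls, DDIT4, a stress-induced inhibitor of mTORC1, was largest, with 34.99 ± 17.5 FPKM in control and 8.48 ± 0.477 FPKM in overexpressing cells (SD, n = 3 each). Its log2 fold change was -1.82 with a standard error of 0.262 (limma, adjusted p = 0.0402). The control values of DDIT4 were 27.9, 22.2 and 54.9 FPKM, and without control replicate 3 the log2 fold change was -1.45. The imprinted noncoding RNA H19 fell by 0.94, from 13.99 ± 2.03 to 6.77 ± 0.212 FPKM (limma, adjusted p = 0.00447). PRSS2 and PRSS1, trypsinogen genes of near-identical sequence on chromosome 7, fell by 1.35 and 1.26. Their reads can be assigned to either copy, so the share of each is uncertain, while the paralog PRSS3 was at 31.1 ± 2.55 and 31.2 ± 1.06 FPKM. The secreted stress cytokine GDF15 fell by 0.53, from 96.9 ± 4.15 to 66.8 ± 3.82 FPKM, and the transcription factor gene MYC by 0.39, from 30.6 ± 1.66 to 23.1 ± 0.430 FPKM. ASS1 of the urea cycle, the palmitoyltransferase gene ZDHHC13, the fatty acid oxidation gene CPT1A and the centriole gene CEP164 fell by 0.54, 0.48, 0.46 and 0.44. The calls for IFI44, GDF15, CADM1, LINC01004, C6orf15, UGT8, NFKBIA, DDIT4, ASS1, ZDHHC13, CPT1A, CEP164 and MYC were each lost when at least 1 of the libraries was left out. These calls and that of H19 (limma, adjusted p = 0.0759) were also lost with no expression filter. DDIT4, NFKBIA and UGT8 lost theirs with quantile normalization and with nuclear-encoded scaling. With no trend, DDIT4, NFKBIA, ASS1 and MYC were not called.

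**Figure D1:**
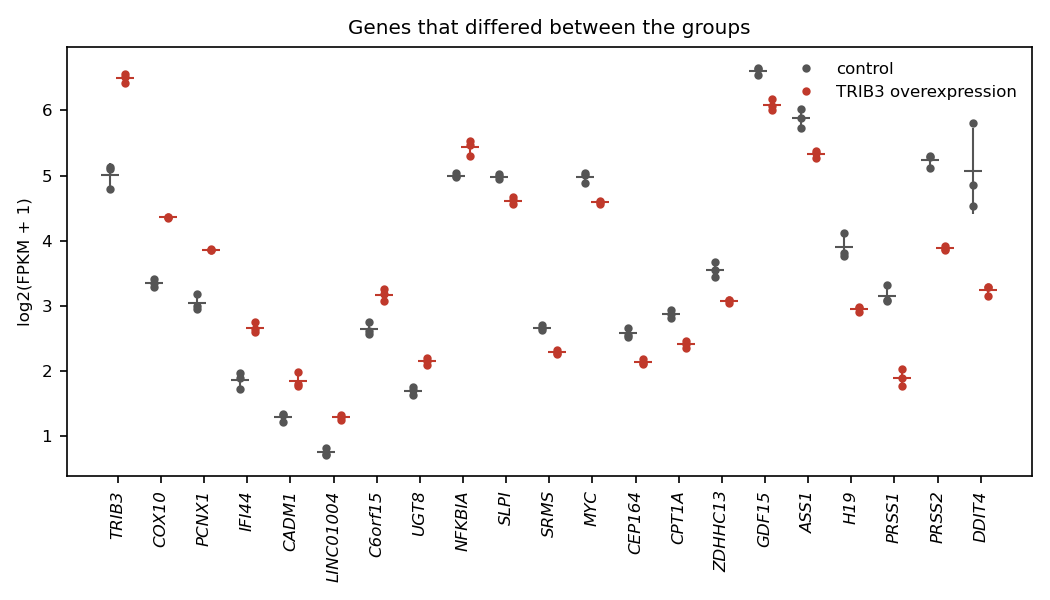
Expression of the 21 called genes as log2(FPKM + 1), ordered by fold change, with each point a library, each horizontal mark the mean of 3 libraries and each vertical bar 1 SD. The groups do not overlap for any of the 21 genes, and DDIT4 has the widest spread in control, from 22.2 to 54.9 FPKM.

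Gene lists fixed before the data were examined were tested with camera at a preset correlation between genes of 0.01. List medians are given without subtracting the median log2 fold change over all tested genes, which was 0.019. That median was 0.005 with median-ratio scaling and 0.004 with nuclear-encoded scaling. Of 25 lists with at least 5 tested members, 4 were higher and 7 lower at adjusted p below 0.05, and 0 and 0 were called with an estimated correlation. Each of the following statements on a list therefore rests on the preset correlation. At that correlation, every grouping that mixed control and overexpressing libraries also called lists, from 4 to 13. A list call alone therefore does not set the real grouping apart. With array weights, chosen after the data were seen, 1 list was higher and 3 were lower. Fry's test for change in either direction gave adjusted p = 0.00193 for the integrated stress response list, 0.00824 for Wnt targets, 0.0109 for interferon-stimulated genes and 0.0176 for heat shock genes. Its test for a shared direction called no list, with adjusted p = 0.412, 0.22, 0.22 and 0.161 for these in that order. A few members can carry the test in either direction, and it was not run on the mixed groupings.

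In the intestinal stem cell list 0 of 9 tested members were called, and adjusted over the list alone TNFRSF19 was higher and CD44 lower. Adjustment over a list alone, here and below, corrects for the members of that list and not for the number of lists. The list did not pass the test, with a median log2 fold change of -0.04 and a camera adjusted p = 0.201 (adjusted p = 0.539 with an estimated correlation). Without control replicate 3 its median was -0.009 (adjusted p = 0.315), and control replicate 3 lay above the other controls in this list by a median of 0.13. Its adjusted p ranged from 0.0716 to 0.481 over the 20 alternatives. LGR5, the receptor that marks crypt base stem cells, was at 26.4 ± 6.48 FPKM in control and 21.8 ± 0.576 FPKM in overexpressing cells (SD, n = 3 each; limma, adjusted p = 0.643), with overlapping groups. Its control values were 26.6, 32.7 and 19.8 FPKM. Without control replicate 3 the log2 fold change of LGR5 moved from -0.24 to -0.42 and was called lower (limma, adjusted p = 0.042), and without control replicate 2 it was -0.07. Over the 20 alternatives its adjusted p ranged from 0.00617 to 0.942, and 2 of them called it. CD24 had a log2 fold change of 0.07, which turned to -0.005 without control replicate 1. The Wnt target list was lower with a median of -0.06 and an adjusted p = 0.0122 (adjusted p = 0.508 with an estimated correlation). Of its 16 members 1, MYC, was called, and adjusted over the list alone 3 were lower, MYC, EPHB3 and CD44, and 1 higher, TNFRSF19. EPHB3 had a log2 fold change of -0.34, CD44 of -0.31 and TNFRSF19 of 0.27. This list was no longer called without control replicate 2 (median -0.065, adjusted p = 0.118) or without control replicate 3 (median -0.047, adjusted p = 0.0692), nor with no expression filter (median -0.028, adjusted p = 0.0762), while its median stayed negative in each.

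The integrated stress response list, targets of ATF4 and CHOP, was lower with a median of -0.07 and an adjusted p = 0.00281 (adjusted p = 0.539 with an estimated correlation). Of its 22 members 2 fell, DDIT4 and GDF15, and 3 were lower when adjusted over the list alone, with CHAC1 at a log2 fold change of -0.63. XPOT, in the same list, had a value of 0.16. The list's median was -0.03 without control replicate 1 (adjusted p = 0.0305) and -0.03 without control replicate 3 (adjusted p = 0.0277), and control replicate 3 lay above the other controls in this list by a median of 0.08. The list of endoplasmic reticulum chaperones had a median of -0.04 and an adjusted p = 0.00281 (adjusted p = 0.713 with an estimated correlation). None of its 19 members was called by limma over all genes, and 1 was, HERPUD1 at -0.36, adjusted over the list alone. SYVN1 was at -0.18, HSP90B1 at -0.14 and SEL1L at -0.09. Its direction turned when control replicate 2 was left out (median 0.03, adjusted p = 0.892).

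Heat shock genes were lower, with a median of -0.13 over 12 members and an adjusted p = 3.91e-08 (adjusted p = 0.496 with an estimated correlation). None was called over all genes and 5 were lower adjusted over the list alone. DNAJB1 was at -0.33, HSPA8 at -0.30, HSPA1B at -0.61 and BAG3 at -0.16, and reads of HSPA1B can also belong to its near-identical copy HSPA1A. Interferon-stimulated genes were higher, with a median of 0.23 over 17 members and an adjusted p = 9.05e-05 (adjusted p = 0.508 with an estimated correlation). IFI44 was the 1 called member, and adjusted over the list alone 8 were higher and 1 lower. IFIT2 was at 0.51, IFIT1 at 0.46 and RSAD2 at 0.37. Control replicate 3 lay above the other controls in this list by a median of 0.16. Whether lentiviral infection alone raised these genes was not tested. The immediate early and ERK target list had a median of -0.09 over 16 members, 0 of them called, and an adjusted p = 0.00106 (adjusted p = 0.539 with an estimated correlation). EGR1 was at -0.48, SPRY4 at -0.27, IER3 at -0.23 and IER2 at -0.17. Without control replicate 3 its median was -0.006 and its adjusted p was 0.477, and the median of the heat shock list was -0.07 without control replicate 2.

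Proliferation lists moved little. The S phase list had a median of 0.06 over 24 members, 0 of them called either way, and an adjusted p = 0.0122 (adjusted p = 0.713 with an estimated correlation), and without control replicate 3 a median of 0.02 and an adjusted p of 0.868. MCM6 was at 0.14, MCM2 at 0.16, RRM1 at 0.09 and CHAF1B at 0.11. The G2 and M phase list had a median of 0.06 over 25 members, 0 called either way, and an adjusted p = 0.0211 (adjusted p = 0.496 with an estimated correlation), with KIF11 at 0.14, CCNA2 at 0.10, AURKB at 0.10 and NDC80 at 0.13. It was not called without control replicate 2 (median 0.038, adjusted p = 0.118) or TRIB3-overexpressing replicate 2 (median 0.048, adjusted p = 0.0786), nor with median-ratio scaling (adjusted p = 0.0521), quantile normalization (adjusted p = 0.161) or nuclear-encoded scaling (adjusted p = 0.0502). Epithelial junction and keratin genes had a median of -0.03 over 17 members, 0 called over all genes, and an adjusted p = 0.0185 (adjusted p = 0.508 with an estimated correlation). ESRP1 at 0.28 and ELF3 at -0.16 passed adjusted over the list alone, CLDN1 and CLDN3 were both at -0.24, and without control replicate 3 the list's median was -0.051 and its adjusted p 0.315. With no expression filter the adjusted p was 0.135.

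Measures of RNA makeup also differed. Mitochondrially encoded genes took 10.4 ± 0.370% of the fragments in control and 9.17 ± 0.450% in overexpressing cells (SD, n = 3 each). All 13 had negative fold changes, with a median of -0.18 and an adjusted p = 2.75e-09 (adjusted p = 0.496 with an estimated correlation), and 0 were called over all genes while 6 passed adjusted over the list alone. Quantile normalization ended the list's call, with a median of 0 and an adjusted p of 0.843, within a range from 4.06e-14 to 0.843 over the alternatives. ND5 was at -0.38, ATP6 at -0.30, ND1 at -0.28 and ND4 at -0.18. Cytosolic ribosomal protein genes took 4.03 ± 0.108% and 4.16 ± 0.0300%, with a median of 0.05 over 76 members, 0 called, and an adjusted p = 0.000561 (adjusted p = 0.713 with an estimated correlation). RPL22L1 was at 0.14, RPL37 at 0.11 and RPS23 at 0.10, and without control replicate 3 the list's median was 0.024 and its adjusted p was 0.244. Control replicate 3 lay apart from the other libraries along the first principal component, which held 37.7% of the variance, at 13.8 against -6.56 to -0.93. The second component, with 28.5%, separated the groups.

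**Figure D2:**
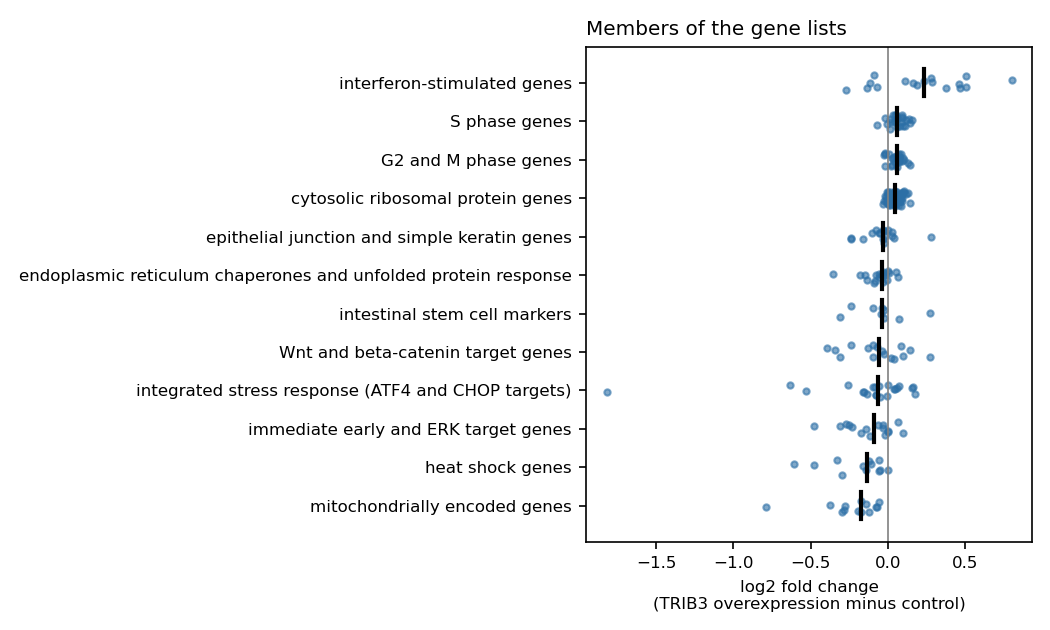
Log2 fold changes of the members of the 11 lists called with the preset correlation and of the intestinal stem cell list, with each point a gene and each vertical bar the median of the list. Medians range from -0.18 for mitochondrially encoded genes to 0.23 for interferon-stimulated genes.

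**Figure D3:**
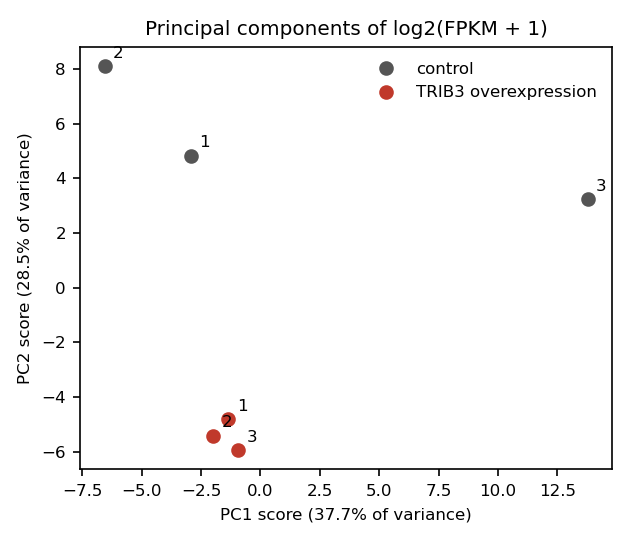
First and second principal components of log2(FPKM + 1) over the 10638 tested genes, with each point a library numbered by its replicate. Control replicate 3 lies at 13.8 on the first axis, and the groups lie on opposite sides of 0 on the second.

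Beside the stem cell list, 13 tested lists did not pass. Counting calls over all genes, NFKBIA was the only called member among the NF-kB list (15 members, adjusted p = 0.122), and 0 members were called in the lists of Wnt pathway components, ribosome biogenesis, cholesterol and fatty acid synthesis, FOXO targets, p53 targets, hypoxia and glycolysis, autophagy and lysosome, TGF-beta targets, YAP targets, Notch pathway, tribbles partners and replication-dependent histones. Their camera adjusted p values were 0.755, 0.38, 0.81, 0.599, 0.627, 0.755, 0.637, 0.377, 0.637, 0.326, 0.504 and 0.637 in that order. Without control replicate 1 the NF-kB list was called lower (median -0.15, adjusted p = 1.01e-05), within a range of adjusted p from 1.01e-05 to 0.935 over the alternatives. Without control replicate 3 the cholesterol list was called higher (median 0.07, adjusted p = 0.0148), within a range from 0.0148 to 0.886. Ribosome biogenesis genes were called higher without control replicate 2 (median 0.10, adjusted p = 0.00197) and lower without control replicate 3 (median -0.06, adjusted p = 0.00152). Adjusted over the list alone, 5 TGF-beta targets were higher, CCN2, ID2, ID3, TGFB2 and TGFBI, as were NFKBIA of the NF-kB list and AMOTL2 of the YAP list, while ICAM1 of the NF-kB list was lower. The median and the camera direction disagreed in sign for the cholesterol list, at 0.03 and lower, and the mean was 0.003 against a median of -0.02 for the hypoxia list and 0.006 against -0.01 for Wnt pathway components. Lists with under 5 tested members were not tested as lists, and 0 of their members were called over all genes, while the goblet marker SPINK4 was lower adjusted over the list alone. They were colonocyte (4), goblet (4), squamous (2), mesenchymal (4), immune (1) and nuclear-retained noncoding RNA (3) genes, and none of the enteroendocrine or fibroblast markers reached the expression minimum.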

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

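Scaling over nuclear-encoded genes, array weights and both voom fits were chosen after the data were seen, and the cause of a change was not tested unless stated. All 21 called genes kept their direction under each of the 20 alternatives. Leaving out a library could not have turned it, because the groups do not overlap for any of the 21. TRIB3, COX10, PCNX1, PRSS2 and PRSS1 also kept their calls in all 20. With the replicate number as a block, 13 genes were called, 6 of them lower, and 12 of the 21 were shared. Same-numbered libraries did not deviate together, with correlations of -0.01, 0.05 and 0.04. This gives no sign that the numbers pair the libraries, but it cannot exclude a pairing. Genes changed numbered 189 with array weights (111 higher, 78 lower), 33 with voom (20 lower) and 364 with voom and quality weights (234 higher, 130 lower). With no filter 14 were called, of which 5 were shared with the 21. Leaving out 1 library gave 6 to 133 genes changed, 3 to 85 higher, 3 to 48 lower and 3 to 6 changed at least 2-fold, with fewer samples in each fit. Genes changed at least 2-fold numbered 8 at a pseudocount of 0.01, 3 with quantile normalization, 3 with nuclear-encoded scaling, 8 with voom and 10 with quality weights. Lists higher numbered 1 with array weights and 1 with quality weights, and lists lower 3 with array weights. CD24 turned to -0.005 without control replicate 1, its range over left-out libraries being -0.005 to 0.135.

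The values that follow are medians of log2 fold changes. With array weights, lists no longer called were endoplasmic reticulum chaperones at -0.006, Wnt targets at -0.073, epithelial junction genes at -0.032, S phase at 0.026, G2 and M phase at 0.042, immediate early genes at -0.041 and ribosomal protein genes at 0.023. With quality weights they were epithelial junction genes at -0.023, S phase at 0.028, G2 and M phase at 0.050 and ribosomal protein genes at 0.027. With no filter, Wnt targets at -0.028 and epithelial junction genes at -0.029 were not called. G2 and M phase genes were not called with median-ratio scaling at 0.039, quantile normalization at 0.031 or nuclear-encoded scaling at 0.038. Mitochondrially encoded genes were at 0 with quantile normalization, which gives the highest ranks of every library the same values. The direction of the test turned for Wnt pathway components with array weights at 0.003 and quality weights at -0.007, for ribosome biogenesis at -0.022 and -0.016, and for cholesterol synthesis at 0.072 and 0.060, and at 0.025 with no filter. It also turned for NF-kB genes with array weights at 0.002, for hypoxia genes with no filter at 0 and array weights at 0.005, and for histone genes with no filter at 0.011 and quality weights at 0.052.

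Over left-out libraries, medians ranged from -0.088 to 0.028 for endoplasmic reticulum chaperones, -0.095 to -0.047 for Wnt targets, -0.028 to 0.009 for Wnt components, -0.058 to -0.023 for epithelial junction genes, 0.020 to 0.095 for S phase, and 0.038 to 0.063 for G2 and M phase. They ranged from -0.061 to 0.097 for ribosome biogenesis, -0.051 to 0.071 for cholesterol synthesis, -0.002 to 0.103 for FOXO targets, -0.148 to -0.020 for NF-kB genes, -0.031 to 0.018 for hypoxia genes and 0.009 to 0.069 for YAP targets. For immediate early genes the range was -0.139 to -0.006, for ribosomal protein genes 0.024 to 0.064 and for histone genes 0.004 to 0.159. Ribosome biogenesis genes were called in opposite directions without control replicate 2 (0.097) and without control replicate 3 (-0.061). NF-kB genes were called lower without control replicate 1 (-0.148) and cholesterol synthesis genes higher without control replicate 3 (0.071). The integrated stress response list stayed called, at -0.029 without control replicate 1 and -0.025 without control replicate 3, as did the heat shock list at -0.070 without control replicate 2. Other called lists that moved by over 1.5 times and stayed called were endoplasmic reticulum chaperones at -0.074 without control replicate 1 and -0.088 without control replicate 3, Wnt targets at -0.095 without TRIB3-overexpressing replicate 3, epithelial junction genes at -0.058 and -0.053 and S phase genes at 0.095 and 0.094 without control replicates 1 and 2, and immediate early genes at -0.139 without control replicate 2. Named genes not called with all libraries in the main test but called with a library left out were LGR5 at -0.424, HERPUD1 at -0.348, IFIT2 at 0.527, IFIT1 at 0.549, DNAJB1 at -0.261, HSPA8 at -0.353 and HSPA1B at -0.431 without control replicate 3, and CHAC1 at -0.773 and EGR1 at -0.684 without control replicate 2. Named genes called in neither fit that moved by over 1.5 times were HSP90B1 (-0.138 to -0.052), SEL1L (-0.088 to -0.056), LGR5 (-0.239 to -0.074) and NDC80 (0.131 to 0.080) without control replicate 2, and CLDN1 (-0.242 to -0.152), MCM2 (0.155 to 0.096), CD24 (0.074 to 0.135) and IER3 (-0.234 to -0.122) without control replicate 3. IER3 was at -0.362 without control replicate 1. Without TRIB3-overexpressing replicate 3, HSP90B1 was at -0.088, CLDN3 at -0.362 and ATP6 at -0.194, and CLDN3 was at -0.158 without TRIB3-overexpressing replicate 2. The stem cell list was at -0.059 to -0.009 over left-out libraries. Over the 20 alternatives, camera adjusted p ranged from 0.0716 to 0.481 for stem cell markers, 0.00271 to 0.118 for Wnt targets, 3.76e-05 to 0.0305 for the integrated stress response, 1.8e-05 to 0.892 for endoplasmic reticulum chaperones and 3.31e-10 to 8.37e-05 for heat shock genes. They ranged from 6.9e-08 to 0.00331 for interferon-stimulated genes, 7.71e-06 to 0.477 for immediate early genes, 0.000286 to 0.868 for S phase, 0.00357 to 0.161 for G2 and M phase, 0.00487 to 0.315 for epithelial junction genes, 5.18e-06 to 0.244 for ribosomal protein genes, 4.06e-14 to 0.843 for mitochondrially encoded genes and 0.00152 to 0.472 for ribosome biogenesis. In simulated data without an outlying library the test recovered 56% of changes of 0.322 on the log2 scale. Recovery of single genes with smaller changes was not measured.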

Other observations

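Every test of control replicate 3 except that of gene length, and every test of COX10, PCNX1 and the pseudoautosomal genes, was chosen after the result was seen. Without control replicate 3, 5 of 17 interferon-stimulated genes, 2 of 13 TGF-beta targets and 1 each of the cholesterol, autophagy and NF-kB lists were called higher, and 3 of 12 heat shock genes, 3 of 22 integrated stress response genes, 2 of 16 Wnt targets, 1 of 19 endoplasmic reticulum chaperones and 1 of 9 intestinal stem cell markers lower, among 133 called genes. The stem cell marker was LGR5, also a Wnt target, at -0.42 (limma, adjusted p = 0.042). RORA, HOXB6 and RUNX2, picked here after their values were seen, had log2 fold changes of 0.44, 0.49 and 0.34 in that fit (limma, adjusted p = 0.00983, 0.0143 and 0.0166), against 0.36, 0.27 and 0.30 with all libraries, where none of the 3 was called.

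Control replicate 3 itself differed from the mean of the other controls in several lists, as a description of 1 library. Ribosome biogenesis genes lay lower by a median log2 difference of -0.32 and S phase genes by -0.16, at the 0 and 0.03 percentiles of 10000 random lists matched on expression. The random lists were drawn gene by gene, so a list whose genes vary together can reach an extreme percentile more easily. Histone genes lay lower by -0.28, at the 0.02 percentile. Immediate early genes lay higher by 0.21, cholesterol synthesis genes by 0.15, interferon-stimulated genes by 0.16, mitochondrially encoded genes by 0.09 and FOXO targets by 0.23, at the 100, 100, 99.98, 99.95 and 99.93 percentiles. NF-kB genes, TGF-beta targets, integrated stress response genes and epithelial junction genes lay higher by 0.15, 0.15, 0.08 and 0.07, at the 99.87, 99.77, 99.53 and 99.26 percentiles, and the other 13 lists lay between the 9.76 and 98.37 percentiles.

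The libraries divide into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 21 genes and the highest other split 1, so 1 of the 10 splits, the real one itself, gave as many. For genes changed at least 2-fold the numbers were 5 and 1, again with only the real split as high. For gene lists the real split called 11 and the other splits from 4 to 13. Here 2 of the 10 splits, the real one included, gave at least as many as the real one.

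The distance of control replicate 3 was set against a lower depth, a label swap and a bias by gene length. Its fragment total differed by -1.53% from the mean of the other 5 libraries, which argues against depth. Its TRIB3 level of 33.3 FPKM lay with the other controls, and no overexpressing library lay at control level, which argues against a swap between the groups. A smooth trend on gene length removed 2.79% of the variance of its deviation (bootstrap SE 0.316), which argues against length bias as the whole cause. The design gives no biological explanation to test, and a difference in culture state stays open and untested.

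COX10 and PCNX1 about doubled with little spread. The expressed genes within 2 Mb of COX10, on chromosome 17 from 14069504 to 14208677, had a median log2 fold change of 0.039 over 12 genes, and those around PCNX1 of 0.008 over 18 genes. The highest neighbour was at 0.188 for COX10 and at 0.142 for PCNX1. These values argue against gain of a segment that takes in the neighbours, but a gain confined to either gene would not show in them. PCNX2, PCNX3 and PCNX4 together lost -3.7% of the counts PCNX1 gained, that is, they gained slightly, which argues against reads moved from them. Gain of either gene alone, reads shared between COX10 and other loci, vector insertion at either gene and an effect of TRIB3 were not tested and stay open.

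Pseudoautosomal genes varied between replicates, by the SD within groups pooled over both. The 4 expressed ones, ASMTL, CD99, SLC25A6 and VAMP7, had a median within-group SD at the 99.8 percentile of equally expressed genes, against 55.5 for 48 X genes next to the boundaries. The ratio of their SD to that of Poisson counting had a median of 18.2, from 3.91 for VAMP7 to 32.2 for CD99, which argues against counting noise. Alignment shared between the X and Y copies may play a part, but 4 genes, of which some prompted the question, cannot decide it, and such sharing alone does not say why libraries of 1 group differ.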
